A study of Homo sapiens with 42 samples.

How the data were processed

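The series holds 42 samples of peripheral blood mononuclear cells, hybridized to 1 Affymetrix array each, in 4 groups named in the labels: 13 controls, 14 patients with active disease, 9 in remission while on medication (CRM) and 6 in remission off medication (CR). The deposited values are probe set summaries on a log2 scale. Per the labels the authors used the affy package, with no version given. The summarisation, background and normalization steps are not stated, and the log base of 2 was inferred from the range of the values. The number of arrays limits the precision, since arrays give no read depth.

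Among the probe sets, 62 are array controls, 11721 carry no gene symbol, 1801 carry several and 41091 carry 1. Of these last, 41037 had an Entrez ID in the RefSeq gene table, and 0 symbols were updated. Genome positions were not used here. Each of 19740 symbols was represented by its probe set with the highest mean over all samples. Genes that could show a person's sex were left out of all tests, because the samples come from people.

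All 42 samples were fitted together in limma 3.58.1 (R 4.3.3) with 1 coefficient per group and no covariate. The 6 pairwise contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05, and an F test covered the contrasts against controls together. Gene lists, 28 in number and covering blood cell types and pathways, were tested with camera at a preset correlation of 0.01, adjusted over 168 tests, and again with an estimated correlation. The lists were also tested with fry, which tests a list on its own, not against other genes, and keeps the correlation between its genes. Overlaps of calls were set beside 100 simulations of unchanged groups and 20 splits of the controls. Other tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, the tests, the lists, the rule for naming genes and a first set of other settings were chosen before the data were examined.

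The naming rule took the 8 largest rises and 8 largest falls among called genes above the median level in each comparison with controls. Between patient groups it took the 5 largest of each, and where fewer than 5 genes passed, the 5 with the smallest p. It added up to 4 members of each called list and of 5 lists named in any case. This gave 445 results for a gene in a comparison. After these had been computed, the printed genes were narrowed to 163: all those of the first kind, 2 members of up to 6 lists, 1 member of the remaining always named lists, and genes called within batches. The tests for single extreme samples and the alternatives for named genes were narrowed to the same 163, also after the wider results had been seen. The totals over the wider set are given with both.

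Several choices were made after the data had been seen. An array was treated as failed when its standard deviation lay more than 5 scaled median absolute deviations below the median. Average-linkage clusters of the other 41 arrays on 12 poly-A spike-in probe sets were used as batches, at 5 and at 3 clusters, with the batch as a block in limma. Cuts at 2 to 5 clusters were looked at. The gaps of the tree favoured 3, and 5 was preferred because controls 1 to 7 then stand alone. The platelet and red cell precursor lists were compared within these batches by 100000 permutations. The genes of the batch fit were named after their values were seen. Results within a single cluster are given as counts of genes only.

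The fit was tested on simulated data with 50 changed genes of each size among 19740. At a log2 change of 0.5 it recovered 78% in active disease against controls, 62% in CRM and 58% in CR, and at a log2 change of 1 it recovered 94%, 90% and 90%. With a simulated batch effect it made 1921 false calls between active disease and controls without a block and 15 with the block. The other settings covered scaling, filters, the choice of probe set, the model, covariates and leaving out each array.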

Results

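Gene expression was measured on Affymetrix arrays in peripheral blood mononuclear cells, the lymphocytes and monocytes left after red cells and granulocytes are spun away. The patients had polyarticular juvenile idiopathic arthritis, a chronic inflammation of many joints that begins in childhood. The 42 samples fell into 4 groups: 13 controls, 14 patients with active disease, 9 in remission while on medication (CRM) and 6 in remission off medication (CR). Each value was a log2 expression level, and 19740 genes were tested. Arrays carry no read depth, so the number of arrays in each group limited the precision.

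The arrays did not form 1 uniform series. On 1 active array, replicate 14, the standard deviation over all probe sets was 1.605, against 2.143 to 2.241 on the other 41. Its mean rank correlation with the other arrays was 0.848, against 0.972 to 0.982. Control transcripts added to each RNA sample before labelling (poly-A spike-ins) were used to cut these 41 arrays into 5 clusters, called spike-in batches here. The gaps between clusters favoured 3, and 5 were used because controls 1 to 7 then stand alone. The 2 high batches had nearly the same mean spike-in level (8.356 and 8.387). The 2 batches with the lowest spike-in level held 6 active and 6 CRM arrays. A middle batch held 2 control, 2 active, 2 CRM and 5 CR arrays. The 2 high batches held controls 1 to 7 alone in 1, and 4 control, 5 active, 1 CRM and 1 CR array in the other. In controls 1 to 7 the ACTB probe set at the 3' end exceeded that at the 5' end by 0.509 ± 0.159 (SD, n = 7), against 0.204 ± 0.0433 (SD, n = 6) in controls 8 to 13. This difference had a two-sided exact permutation p of 0.00117. Batch and group therefore overlapped only in part, and values within batches (batch as a block, without the failed array) are given beside many of the main values. Only active replicates 7 to 13, CRM replicates 7 to 9 and the CR arrays shared a batch with controls. Comparisons with controls within batches rest directly on those arrays and on controls 8 to 13.

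**Figure D1:**
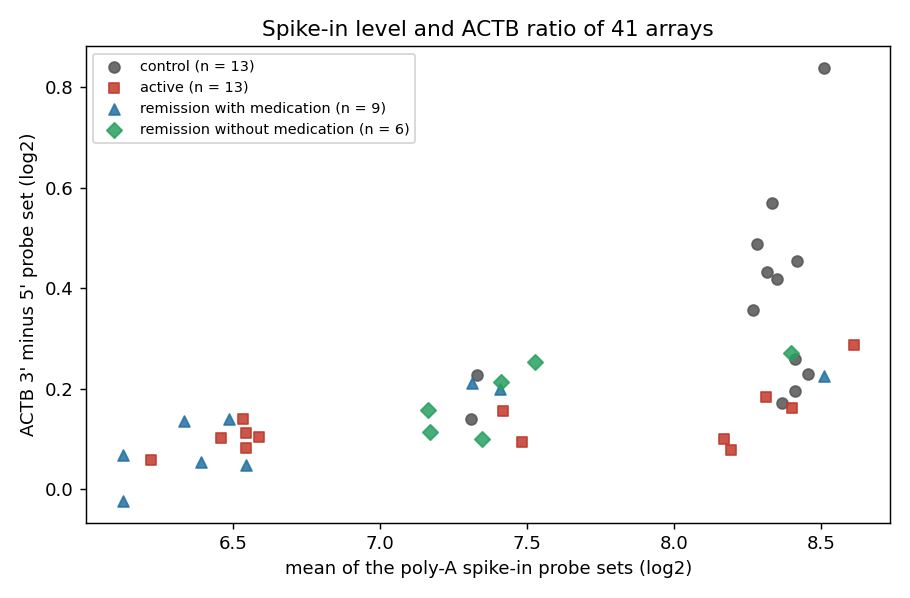
Each point is 1 of the 41 arrays without the failed one. The horizontal axis is the mean log2 level of the poly-A spike-in probe sets, the vertical axis the log2 difference between the 3' and 5' ACTB probe sets, and colours give the group. Arrays form a low, a middle and a high spike-in cluster, and controls 1 to 7 lie at the top right with a mean ACTB difference of 0.509.

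Active disease was compared with controls first. Genes of platelets and red cell precursors were the most raised and genes of cytotoxic lymphocytes the most lowered. MYL9, a myosin light chain abundant in platelets, rose 4.88-fold, from 6.81 ± 0.806 (SD, n = 13) in controls to 9.1 ± 1.1 (SD, n = 14) in active disease. The other large rises were ALAS2, the first enzyme of haem synthesis in red cell precursors (3.43-fold), MPIG6B, a platelet and megakaryocyte receptor (3.27-fold), and TMEM158 (2.82-fold). ITGB3 and ITGA2B, the subunits of the platelet fibrinogen receptor, rose 3.17-fold and 2.47-fold. TRIM58, a gene of late red cell precursors, rose 2.51-fold and PARVB 2.42-fold. The largest fall was that of A2M-AS1 (2.29-fold, log2 difference -1.20, SE 0.3). GZMK, a granule protease of T and NK cells, fell 2.15-fold, and the NK cell receptors KLRC3, KLRB1, KLRF1 and KLRD1 fell 2.13, 2.03, 1.95 and 1.94-fold. AKR1C3, an aldo-keto reductase, fell 2.13-fold and LRRN3 fell 2.0-fold. Adjusted p over these 16 genes ran from 0.000542 for MYL9 and MPIG6B to 0.0393 for KLRF1.

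Within spike-in batches none of these 16 passed the test. The platelet genes kept most of their size: MYL9 stood at 1.99 log2 units (SE 0.458, adjusted p = 0.38), ITGB3 at 1.66 (SE 0.436) and ITGA2B at 1.31 (SE 0.341), the last 2 with adjusted p = 0.423. These values leave out the failed array, which the folds above include. With that array left out in both fits, MPIG6B went from 1.80 with no block to 1.26 within batches. The NK receptors lost most of theirs. KLRB1 went from -1.02 to -0.31 (SE 0.242) and KLRF1 from -0.96 to -0.27 (SE 0.378).

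By gene list, 14 of 28 platelet genes rose in active disease and none fell, 20 when adjusted over the list alone. The counts were 25 and 26 without the failed array, and within batches 0 and 12. The median platelet difference was 0.84 log2 units, 0.97 without the failed array and 0.64 within batches. The test that sets a list against all other genes (camera) gave the platelet list an adjusted p of 1.68e-12. That call was lost with adjusted p = 0.824 with an estimated correlation. Of 25 red cell precursor genes 8 rose, 16 when adjusted over the list alone, with a median of 0.71 and 0.57 within batches (camera adjusted p = 4.15e-09; adjusted p = 0.824 with an estimated correlation). OSBP2 of this list rose 1.64-fold (adjusted p = 0.00471). The rises in the red cell list were 11 and 19 over the list alone without the failed array, and within batches 0 and 3. Of 25 cytotoxic and NK cell genes 8 fell, 17 when adjusted over the list alone. These were 9 and 11 without the failed array and 0 and 0 within batches. Their median was -0.72, -0.55 without the failed array and -0.23 within batches (camera adjusted p = 1.43e-08; adjusted p = 0.824 with an estimated correlation).

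Of 24 B cell genes, 2 rose and 8 when adjusted over the list alone (median 0.26, camera adjusted p = 0.000267; adjusted p = 0.855 with an estimated correlation). BLK, a kinase of B cell receptor signalling, rose 1.64-fold and CD22 rose 1.41-fold. Leaving out the failed array gave 5 rises in the B cell list and 12 over the list alone. Within batches none passed, the list was not called (adjusted p = 0.891), its median was -0.00859, and the BLK difference was 0.0022 (SE 0.219). Controls 1 to 7, the batch of controls alone, had a median of the same list 0.64 below that of controls 8 to 13. Of 46 genes of mitochondrial oxidative phosphorylation, 6 fell and 9 when adjusted over the list alone, and of 39 ribosomal protein genes 3 fell and 5 when adjusted over the list alone. UQCRB and COX5B, subunits of respiratory complexes, fell 1.24-fold and 1.19-fold, and RPL12 and RPL9 fell 1.15-fold and 1.1-fold. In the fit of 41 arrays, which lacks the failed array, 15 genes of each list fell, 25 and 22 over the list alone, and within batches none passed. The medians of both lists depended on the failed array as well. They were -0.31 and -0.46 with it, -0.13 and -0.0982 without it, and -0.0444 and -0.0544 within batches. Camera gave both lists adjusted p of 7.44e-09 and 1.07e-07; adjusted p = 0.855 for both with an estimated correlation.

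Granulocyte granule genes and genes of mature neutrophils had medians of 0.33 and 0.54, with none of 22 and none of 21 genes passing, adjusted over the list alone or over all genes. Camera gave adjusted p of 0.00358 and 0.00909 (adjusted p = 0.855 and 0.862 with an estimated correlation). Within batches the medians were 0.15 and 0.27, and neither list was called (adjusted p = 0.292 and 0.0568). The granule gene LCN2 stood 0.72 higher (SE 0.264, adjusted p = 0.0889). Camera, a two-sided test, also called dendritic cell and T cell genes lower, with medians of -0.21 and -0.19 (adjusted p = 0.824 and 0.89 with an estimated correlation). Without the failed array neither was called, at adjusted p = 0.0682 and 0.36, and the medians were -0.19 and -0.0385. Within batches both were called (adjusted p = 0.00454 and 0.0375, and 0.563 and 0.882 with an estimated correlation). The lists of type I interferon, TNF and NF-kB, glucocorticoid response and monocyte genes were not called. Within batches camera called glucocorticoid response (21 of 25 genes higher, adjusted p = 0.00239) and TNF and NF-kB (25 of 35 higher, adjusted p = 0.0191) higher. With an estimated correlation these were 0.656 and 0.793. It also called immediate early (25 of 28 higher, adjusted p = 2.63e-06), cell cycle (31 of 31 higher, 8.6e-06) and MHC class II genes (16 of 16 lower, 2.56e-05) there. With an estimated correlation those were 0.563, 0.793 and 0.47. KLF9, a glucocorticoid-induced transcription factor, fell by 0.57 log2 units (adjusted p = 0.0244), and RELB, an NF-kB subunit, rose 1.37-fold (adjusted p = 0.0148). LY6E, induced by interferon, stood at 0.41 (SE 0.234) and MS4A7, a monocyte gene, at -0.76 (SE 0.324), neither passing. Within batches KLF9 stood at 0.0334 (SE 0.14), LY6E at -0.0495 and MS4A7 at 0.00776.

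Camera called 10 of 28 lists in active disease, 8 of them also without the failed array and 7 within batches in the same direction. It called 0 with an estimated correlation, in this and every other comparison, with or without the block. In all, limma with Benjamini-Hochberg adjustment called 1138 genes in active disease, 49.9% of them higher and 570 lower. When the arrays were quantile-normalized again the split was 846 higher and 373 lower. Without the failed array 2454 genes were called, and leaving out 1 other array at a time gave 703 (without control replicate 3) to 1386. With 5 spike-in batches as a block limma called 0 genes, with 1254 at an unadjusted p under 0.05, and with 3 batches, where controls 1 to 7 share a batch with patients, 757. Without controls 1 to 7 and the failed array it called 9. Of the 1138 genes, 1093 kept their direction within batches, where their median difference was 0.14 log2 units against 0.352 in the fit of all arrays. The genes were selected in that fit and the arrays are largely the same, so kept direction and a smaller difference are partly built in.

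**Figure D2:**
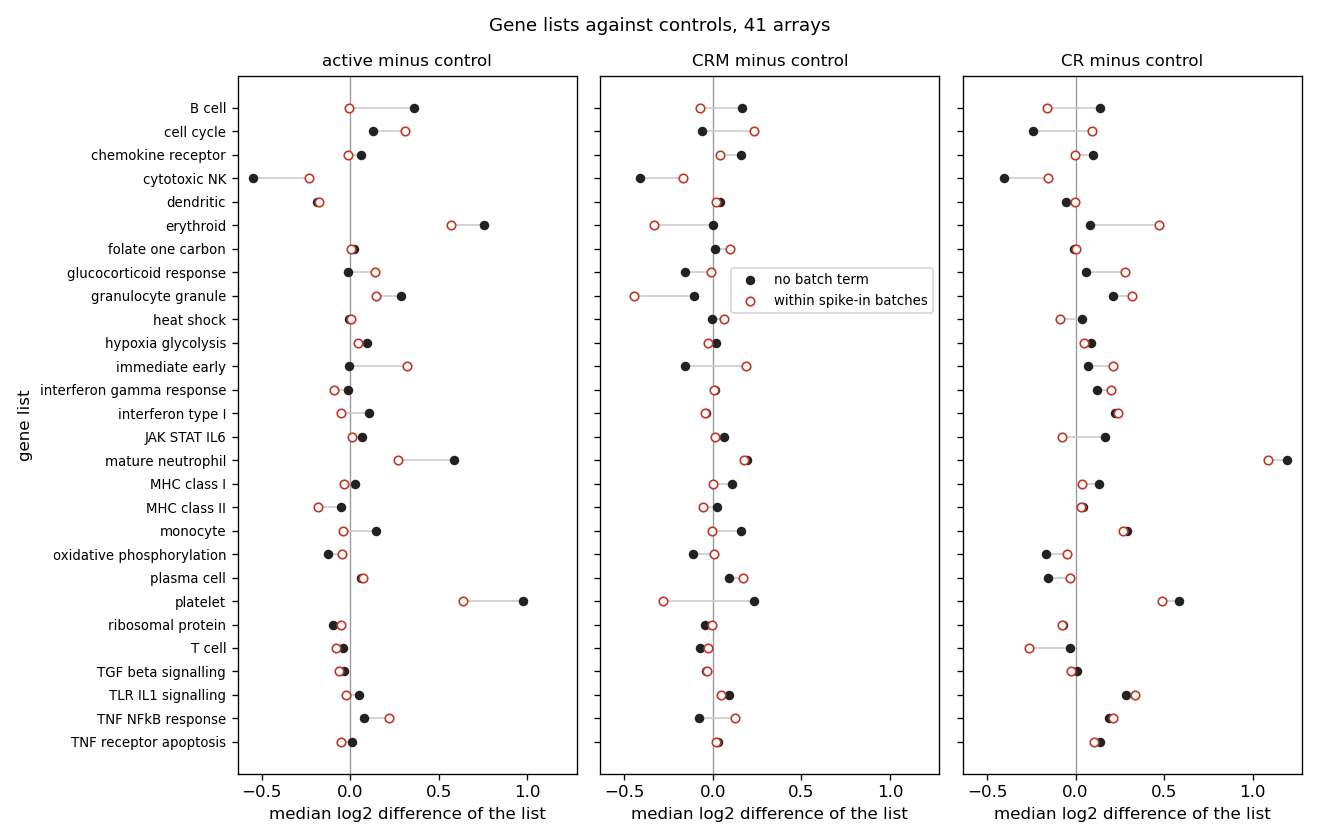
For each of 28 gene lists, filled points give the median log2 difference from controls over 41 arrays and open points the same within spike-in batches, with 1 panel for each patient group. In active disease the platelet list lies at 0.97 and 0.64, and in CR the mature neutrophil list lies at 1.19 and 1.09, while the B cell list moves to 0 or below in all 3 panels.

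Patients in remission with medication differed from controls in 187 genes, 125 higher and 62 lower. The largest fall was in RGS1, a regulator of G protein signalling induced on lymphocyte activation, from 7.63 ± 1.21 (SD, n = 13) to 5.65 ± 0.932 (SD, n = 9). This was 3.94-fold (log2 difference -1.98, SE 0.517, adjusted p = 0.0487). MAFF, an early response transcription factor, fell 2.31-fold. TKTL1, a transketolase-like protein, fell 1.91-fold and CDC14A, a cell cycle phosphatase, 1.86-fold. KLF9 fell 1.61-fold, VTI1A 1.5-fold, and MBNL2, a splicing regulator, and ZHX1 each fell by 0.57 log2 units. The largest rises were in UNC93B1, which carries Toll-like receptors to endosomes (1.82-fold), CLPTM1 (1.79-fold), UBXN11 (1.67-fold) and SEMA4B (1.63-fold). FIZ1 rose 1.58-fold, KCNN4, a calcium-activated potassium channel, 1.54-fold, and BTBD2 and SCAMP4 each 1.53-fold. Adjusted p over these 16 genes ran from 0.00956 for FIZ1 to 0.0491 for UBXN11.

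None of these passed within batches. That comparison rests directly on controls 8 to 13 and on CRM replicates 7 to 9, the CRM arrays that shared a batch with controls. Against 0.381 log2 units in the fit of all arrays, the median difference of the 187 genes within batches was 0.114. There RGS1 stood at -0.0807 (SE 0.616), MAFF at -0.012 (SE 0.319), UNC93B1 at 0.0282 (SE 0.203) and CLPTM1 at 0.13 (SE 0.093). UBXN11 turned to -0.10 (SE 0.154), while KCNN4 stayed at 0.42 of 0.62 (SE 0.199) and TKTL1 at -0.39 of -0.94 (SE 0.253). Without controls 1 to 7 and the failed array, TKTL1 stood at -0.69, CDC14A at -0.61, VTI1A at -0.57 and ZHX1 at -0.48, with none passing. RGS1 and MAFF were also 2.03 and 1.32 log2 units higher in controls 1 to 7 than in controls 8 to 13.

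Camera called 5 of 28 lists between CRM and controls, 1 of them also within batches in the same direction, and 0 with an estimated correlation. Cytotoxic and NK cell genes were lower, with a median of -0.41 and none of 25 genes passing, also adjusted over the list alone (camera adjusted p = 4.94e-06; adjusted p = 0.855 with an estimated correlation). Their median within batches was -0.17. KLRF1 stood at -0.91 (SE 0.326) and GZMK at -0.72 (SE 0.265). Of 28 immediate early genes 2 fell, 3 when adjusted over the list alone, and of 25 glucocorticoid response genes 1 fell by either count. Their medians were both -0.16 (camera adjusted p = 0.00353 and 0.00719; adjusted p = 0.855 for both with an estimated correlation). Leaving out the failed array, 3 and 2 fell, 3 and 5 over the list alone. Within batches these medians were 0.19 and -0.00856, the first list was called higher (adjusted p = 0.000543; adjusted p = 0.69 with an estimated correlation) and the second was not called. DDIT4, a stress response gene of the glucocorticoid list, stood at -1.05 (SE 0.356, adjusted p = 0.128), and at 0.21 within batches. Genes of oxidative phosphorylation had a median of -0.11 and B cell genes one of 0.16, with no gene of either passing (camera adjusted p = 0.00336 and 0.0301; adjusted p = 0.89 for both with an estimated correlation). Of the first list 7 genes fell and 1 rose without the failed array, with 16 lower and 2 higher over the list alone. Within batches its median was 0.00783 and it was not called (adjusted p = 0.987), while the B cell median turned to -0.0718 and was called lower (adjusted p = 0.0404; adjusted p = 0.882 with an estimated correlation). In the first list UQCRB stood at -0.26 (SE 0.0731) and ATP5MG at -0.15 (SE 0.0489). In the second BLK stood at 0.65 (SE 0.247) and TNFRSF13C, the BAFF receptor, at 0.33 (SE 0.116). TNF itself stood 0.76 higher (SE 0.224, adjusted p = 0.0796) and 0.80 within batches (SE 0.29). LY6E, ITGAM and LTF stood at 0.40, 0.28 and -0.81, with none passing, and at -0.0232, -0.10 and -1.58 within batches.

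The 187 calls in CRM became 976 without the failed array, through the shared estimate of the spread, and 0 with 5 or 3 batches as a block (498 and 2313 at an unadjusted p under 0.05). They became 8 without CRM replicate 3 and 378 without CRM replicate 9, and 6 without controls 1 to 7 and the failed array. After a second quantile normalization 112 of 137 calls were higher.

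In remission without medication, 65 genes differed from controls, 42 higher and 23 lower. SIRPB1, a receptor of myeloid cells, rose 2.25-fold, from 7.2 ± 0.634 (SD, n = 13) to 8.36 ± 0.379 (SD, n = 6). NCF1, a subunit of the phagocyte NADPH oxidase whose sequence is shared with near-identical pseudogenes, rose 2.18-fold. NRROS, a regulator of that oxidase, rose by 1.10 log2 units, and TFEB, the transcription factor of lysosomal genes, 2.02-fold. STRN4 rose 2.0-fold, PRAM1, an adaptor of myeloid cells, 1.87-fold, ARL11 1.83-fold and SEMA4B 1.8-fold. The largest falls were smaller: MBNL2 1.71-fold, PGM5-AS1 1.56-fold, DNAJC1 1.55-fold, SELENOI 1.47-fold, GPALPP1 1.44-fold and CFAP97 1.41-fold. LOC285847 and UQCC6 fell by 0.56 log2 units. Adjusted p over these 16 genes was 0.0216 to 0.043. All 65 genes, selected in the fit of all arrays, kept their direction within batches, where none passed. The median difference there was 0.231 log2 units against 0.597 in the fit of all arrays, and the differences of TFEB and UQCC6 were 0.46 (SE 0.135) and -0.40 (SE 0.12).

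The list with the largest shift in CR was that of mature neutrophils, with a median of 1.19 log2 units and 1.09 within batches. All 21 genes were higher, none passed over all genes tested, and 13 passed adjusted over the list alone (camera adjusted p = 2.93e-12; adjusted p = 0.808 with an estimated correlation). TNFRSF10C, a decoy receptor on neutrophils, stood 1.98 higher (SE 0.648) and CXCR2, their chemokine receptor, 1.69 higher (SE 0.503). Controls 1 to 7 had TNFRSF10C 1.59 log2 units and the median of this list 0.63 below controls 8 to 13. Platelet genes had a median of 0.58, with all 28 higher, none passing over all genes and 1 adjusted over the list alone (camera adjusted p = 6.52e-08; adjusted p = 0.855 with an estimated correlation). Its members PF4V1 and MYL9 stood 1.75 (SE 0.49) and 1.37 (SE 0.458) higher. Genes of Toll-like and IL-1 receptor signalling had a median of 0.28, and those of TNF receptors and apoptosis 0.14. No gene of either passed over all genes, and 0 and 4 passed adjusted over the list alone (camera adjusted p = 0.000408 and 0.00123; adjusted p = 0.855 and 0.824 with an estimated correlation). With the failed array left out, 4 genes of each passed over all genes, and 7 and 4 over the list alone. Members were TLR6 (0.56, SE 0.181), IL1RN (0.87, SE 0.304), TNF (0.98, SE 0.255) and TNFRSF10B (0.37, SE 0.108). Cytotoxic and NK cell genes had a median of -0.40 and -0.15 within batches, with none passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00249; adjusted p = 0.855 with an estimated correlation). KLRB1 and GZMK of this list stood at -0.97 (SE 0.289) and -0.86 (SE 0.301).

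Granulocyte granule and type I interferon genes had medians of 0.21 and 0.22 in CR, with MMP9 at 1.87 (SE 0.502), ARG1 at 1.17 (SE 0.421) and IFIT3 at 1.66 (SE 0.615). None passed over all genes, and 1 and 0 passed adjusted over the list alone (both camera adjusted p = 0.00336; adjusted p = 0.855 and 0.89 with an estimated correlation). Monocyte genes, with ITGAM at 0.56 (SE 0.187), had a median of 0.29 (camera adjusted p = 0.0115; adjusted p = 0.862 with an estimated correlation). With the failed array left out, 2 neutrophil genes, 3 platelet genes, 1 granule gene and 2 monocyte genes rose over all genes, and 17, 4, 1 and 2 over the list alone. Of cytotoxic and NK cell genes 1 rose and 1 fell, 1 and 2 over the list alone. Within batches no gene of these lists passed, over all genes or over the list alone, and the TNF receptor and cytotoxic lists were not called (adjusted p = 0.19 and 0.187). The medians there were 0.49 for platelet, 0.34 for Toll-like and IL-1 receptor, 0.11 for TNF receptor, 0.32 for granule, 0.24 for interferon and 0.27 for monocyte genes. KLF9 stood at -0.46 (SE 0.202) and at 0.0406 within batches. Camera called 15 of 28 lists in CR, 9 of them also within batches in the same direction. It called 0 with an estimated correlation. The 65 calls became 1196 without the failed array, 0 with 5 or 3 batches as a block (1439 and 2551 at an unadjusted p under 0.05), 235 among genes above the median level, 0 without CR replicate 1 and 349 without control replicate 10. After a second quantile normalization the calls were 37, with 19 higher.

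Calls were shared between the patient groups, all 3 compared with the same controls. Of the 1138 genes called in active disease and the 187 in CRM, 130 were called in the same direction. Independent lists would share 3.6 higher and 1.79 lower genes. In a simulation, unchanged groups set against the same controls shared 0, which was nearly fixed in advance, as few genes are called where none changed. The fold changes correlated across genes at 0.699, against 0.445 in that simulation, with covariances of 0.0273 and 0.00476. When the controls were split at random between both comparisons, 20 times, the shared calls had a median of 42.5 and ran from 0 to 180. Active disease and CR shared 43 calls, against 1.21 higher and 0.664 lower in independent lists, with a correlation of 0.575 (simulated 0.393) and a covariance of 0.0277 (simulated 0.00461). CRM and CR shared 13, against 0.266 and 0.0722, with a correlation of 0.619 (simulated 0.329) and a covariance of 0.0238 (simulated 0.00441). After splitting the controls the medians were 129.5 (0 to 205) and 25 (0 to 84). The simulation and the splits took no account of the batches. Controls 1 to 7 had no patient in their batch, and with the 5 batches as a block 0 genes were called in each of the 3 comparisons, so batch is an untested source of the shared calls.

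Patients with active disease and in CRM were compared within the disease. In the fit of all 42 arrays limma called 0 genes, with 826 at an unadjusted p under 0.05. The 5 genes with the smallest p, none passing, were ALDH1A1, a retinaldehyde dehydrogenase (-1.04, SE 0.213, adjusted p = 0.334), AFDN (-0.81, SE 0.179), TFPI, the inhibitor of tissue factor (1.11, SE 0.275), UBAP2 (-0.28, SE 0.0696) and RAPH1 (-0.66, SE 0.174). Platelet and red cell precursor genes were higher in active disease as lists. All 28 platelet genes and 24 of 25 red cell precursor genes were higher, with medians of 0.57 and 0.65 (camera adjusted p = 3.68e-18 and 1.48e-21; adjusted p = 0.808 and 0.75 with an estimated correlation). None passed over all genes, and 0 and 16 passed adjusted over the list alone. Without the failed array, with no block, the medians were 0.72 and 0.76, and 26 and 17 passed over the list alone.

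The fits within spike-in batches also left out the failed array, and their medians were 0.98 and 0.87. In a fit of active and CRM arrays alone, the mean of the platelet list was 1.04 log2 units higher in active disease than in CRM (SE 0.239, within-batch permutation p = 0.00015, adjusted over 28 lists 0.0042). It was higher in each of the 4 batches that held both groups, by 2.13, 0.626, 0.84 and 1.25. These batches held 1, 5, 2 and 5 active and 3, 3, 2 and 1 CRM arrays, so 2.13 rests on a single active array and 1.25 on a single CRM array. In the fit of all 41 arrays the difference was 0.991 (SE 0.241). The red cell precursor list was 0.95 higher (SE 0.287, permutation p = 0.00426, adjusted 0.0596). With the 5 batches as a block, a fit chosen after seeing the data, limma called 109 genes, 103 higher and 6 lower in active disease. Of 28 platelet genes 9 were among them and of 25 red cell precursor genes 5 (Fisher's exact test, adjusted p = 6.04e-13 and 3.19e-06). That test treats genes as independent, and camera with an estimated correlation within batches (0.737 and 0.513) gave adjusted p = 0.104 for both lists. All 28 platelet and 22 red cell precursor genes passed adjusted over the list alone. ALAS2 was 4.44-fold higher (log2 2.15, SE 0.521), TMEM158 2.91-fold, MPIG6B 2.69-fold, PROS1, the anticoagulant protein S, 2.62-fold, XK 2.62-fold, CLU 2.58-fold, and ITGA2B and TREML1, a receptor of platelet granules, 2.56-fold. Further members of both lists were SPARC (2.32-fold), HBQ1 (2.2-fold), F13A1 (2.12-fold), DMTN (2.08-fold), GP9 (1.9-fold) and OSBP2 (1.68-fold). The 6 lower genes included ALDH1A1 (log2 -1.09, SE 0.225), CACNA2D3 (-0.70, SE 0.165), RUFY3 (-0.45, SE 0.0823), NOTCH2NLA, which has near-identical copies (-0.42, SE 0.0737), and UBAP2 (-0.30, SE 0.0698). Adjusted p over these named genes was 0.0154 to 0.042.

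The 109 calls depended on the batches and on single arrays. Limma called 0 genes without a block, 5 with 3 batches as a block, 28 with array weights, 13 with active and CRM arrays alone, 0 without active replicate 1 or CRM replicate 9, and 200 without active replicate 8. The platelet genes among them were 0 without active replicate 1, 2 or 7 or CRM replicate 5, 7 or 9, and 19 without active replicate 8. The platelet difference was less dependent, from 0.825 (SE 0.235) without active replicate 1 to 1.17 (SE 0.228) without active replicate 8.

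**Figure D3:**
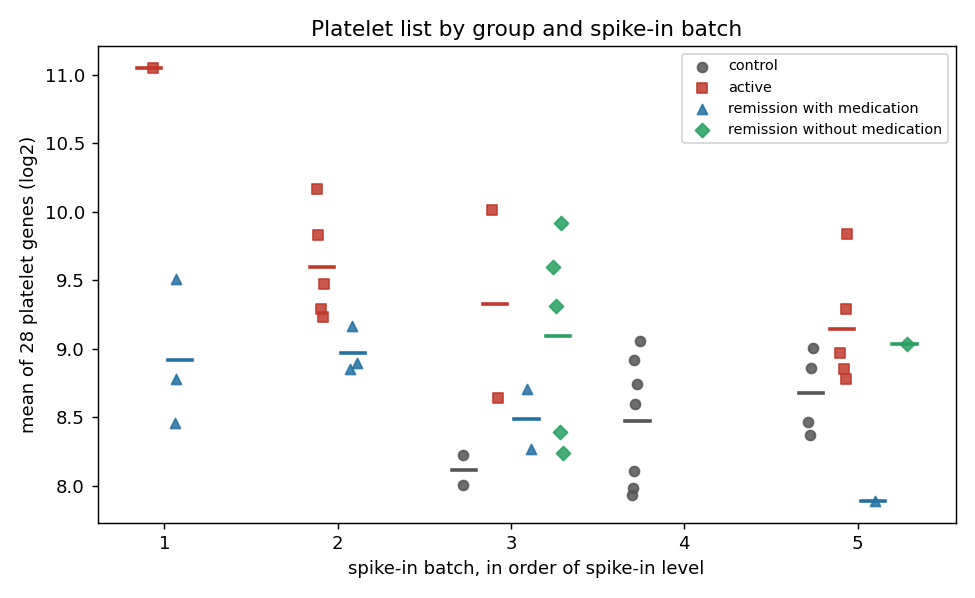
Each point is 1 array, the vertical axis is the mean log2 level of 28 platelet genes, the horizontal axis the spike-in batch in order of spike-in level, and short lines are group means within a batch. In each of the 4 batches with both groups the active mean lies above the CRM mean, by 0.626 to 2.13.

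Camera called 18 of 28 lists between active disease and CRM, 11 of them also without the failed array and 9 within batches in the same direction. It called 0 with an estimated correlation. Besides platelet and red cell precursor genes it called granulocyte granule genes higher in active disease than in CRM (median 0.44, 0.54 within batches; adjusted p = 1.17e-09; adjusted p = 0.808 with an estimated correlation). LCN2 stood at 0.75 (SE 0.293) and AZU1 at 0.59 (SE 0.268). Dendritic cell genes were lower (median -0.25, and -0.17 without the failed array), with IL3RA at -0.57 (SE 0.158) and CD1C at -0.49 (SE 0.186). Camera gave this list adjusted p = 3.7e-05, and 0.75 with an estimated correlation. None of its 15 genes passed over all genes, and 1 was lower adjusted over the list alone. Within batches its median was -0.19 and camera called it lower (adjusted p = 0.000497, and 0.47 with an estimated correlation). There the 1 gene that passed over all genes was higher, while over the list alone 1 was higher and 4 lower. Ribosomal protein and oxidative phosphorylation genes had medians of -0.41 and -0.20 (camera adjusted p = 2.19e-07 and 1.01e-05; adjusted p = 0.855 for both with an estimated correlation). These were -0.041 and -0.0242 without the failed array, where the second list was not called (adjusted p = 0.393). RPL3, RPL38, ATP5F1B and ATP5F1C stood at -0.11, -0.0921, -0.20 and -0.12. Other members with no call were DDIT4 (0.61, SE 0.351), TNF (-0.54, SE 0.221), CX3CR1 (-0.68, SE 0.383), TRIM22 (-0.59, SE 0.497), TRIM58 (1.07, SE 0.296) and MYL9 (1.17, SE 0.396). Without the failed array TRIM22 stood at -0.0508.

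Active disease and CR did not differ in any single gene that passed (0 called by limma, 1892 at an unadjusted p under 0.05, 1 called without the failed array). The smallest p belonged to CDC42SE1 (-0.68, SE 0.135, adjusted p = 0.182), KMT2C, a histone methyltransferase (-0.39, SE 0.0828), ATG16L2 (-1.04, SE 0.242), TMEM192 (-0.39, SE 0.0893) and LHFPL4 (0.42, SE 0.0982). Camera called 21 of 28 lists, 17 of them also without the failed array and 10 within batches in the same direction, with 0 called at an estimated correlation. Of these 21 lists 19 were lower in active disease, lists of innate immune genes among them, and 2 were higher. Mature neutrophil genes had a median of -0.65 and -0.72 within batches, with all 21 lower, and Toll-like and IL-1 receptor genes -0.31 and -0.35 (camera adjusted p = 4.32e-06 and 4.87e-06; adjusted p = 0.855 and 0.824 with an estimated correlation). CXCR2 stood at -1.08 (SE 0.497), CSF3R, the G-CSF receptor, at -0.87 (SE 0.396), TLR6 at -0.47 (SE 0.179) and IL18 at -0.39 (SE 0.145). Interferon gamma response genes had a median of -0.29 and -0.30 within batches (camera adjusted p = 1.26e-05; adjusted p = 0.824 with an estimated correlation), with SECTM1 at -0.57 (SE 0.211) and CIITA at -0.44 (SE 0.164). With the failed array left out and no block, the medians were -0.57 for mature neutrophil, -0.20 for Toll-like and IL-1 receptor and -0.19 for interferon gamma response genes.

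Genes of TNF receptors and apoptosis had a median of -0.20 (camera adjusted p = 4.1e-06; adjusted p = 0.808 with an estimated correlation), with TNF at -0.76 (SE 0.253) and MAP3K14 at -0.40 (SE 0.145). Red cell precursor and cell cycle genes were higher in active disease, with medians of 0.46 and 0.30 (camera adjusted p = 2.04e-06 and 4.77e-05; adjusted p = 0.855 for both with an estimated correlation). Within batches these medians were 0.0926 and 0.21, and the red cell list was not called (adjusted p = 0.308). Their members HBQ1, OSBP2, CENPF and ZWINT stood at 0.98, 0.63, 0.66 and 0.59. IFIT3, MMP9, FKBP5 and ITGAM stood at -1.47, -1.10, -0.63 and -0.39. No gene of the cell cycle, neutrophil, Toll-like receptor, interferon gamma or TNF receptor lists passed, adjusted over the list alone or over all genes. In the red cell list 1 passed adjusted over the list alone.

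The remission groups did not differ in any single gene either (0 called by limma, 1547 at an unadjusted p under 0.05). The smallest p belonged to TBXT (0.40, SE 0.0802, adjusted p = 0.192), MACROH2A2 (0.36, SE 0.0849), LINC03016 (0.34, SE 0.0805), TUFT1 (-0.50, SE 0.118) and ACTG1P17 (0.29, SE 0.0676). Camera called 15 of 28 lists, 10 of them also within batches in the same direction, with 0 called at an estimated correlation. Mature neutrophil genes were lower in CRM than in CR, with all 21 lower and a median of -0.86, -0.97 within batches (camera adjusted p = 5.92e-15; adjusted p = 0.808 with an estimated correlation). ANXA3 stood at -1.74 (SE 0.622) and CXCR2 at -1.48 (SE 0.537). Granulocyte granule genes had a median of -0.39 and platelet genes -0.29 (camera adjusted p = 3.16e-06 and 6.72e-06; adjusted p = 0.824 and 0.855 with an estimated correlation). Within batches these were -0.77 and -0.79, and 3 and 16 genes were lower adjusted over the list alone. MMP9 stood at -1.59 (SE 0.536), ARG1 at -1.19 (SE 0.45), PF4V1 at -1.32 (SE 0.523) and CLEC1B at -0.88 (SE 0.431).

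Immediate early genes had a median of -0.31 between CRM and CR and -0.0455 within batches, where the list was not called (camera adjusted p = 4.78e-06; adjusted p = 0.824 with an estimated correlation), with JUN at -1.53 (SE 0.484) and ZFP36 at -0.38 (SE 0.193). Type I interferon and interferon gamma response genes had medians of -0.24 and -0.15 (camera adjusted p = 2.92e-05 and 0.000102; adjusted p = 0.855 for both with an estimated correlation), with IFIT3 at -1.45 (SE 0.657), IFIT2 at -1.06 (SE 0.577), BATF2 at -0.75 (SE 0.292) and SECTM1 at -0.57 (SE 0.228). FKBP5, TNFAIP6 and FPR1 stood at -0.61, -1.25 and -0.55. None of these members passed.

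Over all 4 groups together an F test in limma called 561 genes, 2111 without the failed array and 3 with the 5 batches as a block.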

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

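All tests of the batches, of the ACTB ratio and of the platelet pattern were chosen after the result was seen, and the random splits of the samples were planned. In CRM (9 samples) and CR (6 samples), 204 sets of values were tested for 1 sample far from the others, and 23 had one where chance gives 10.2. The genes tested were narrowed to the printed ones after a wider set had been seen, in which 56 of 439 had one where chance gives 22. Values below are the gap to the nearest sample as a share of the group's range.

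In CRM 1 sample lay apart from the others on the high side for genes of neutrophils and their granules: ARG1 (0.797), LTF (0.723), MMP9 (0.635), CXCR2 (0.611), AZU1 (0.588) and ANXA3 (0.571). The same held for the list means of granulocyte granule (0.859), mature neutrophil (0.756), type I interferon (0.623), glucocorticoid response (0.588) and Toll-like and IL-1 receptor genes (0.576). Single genes among the rest were IFIT3 (0.626), FKBP5 (0.595), TNFAIP6 (0.594), IFIT2 (0.542), IL3RA (0.518) and TRIM22 (0.509). Each value was tested on its own, so the high sample need not be the same throughout. The low sample was CRM replicate 3 for the mean rank correlation with other arrays (0.684). For the mean of the hybridization spike-ins (0.71) it was CRM replicate 2. In CR the hybridization spike-ins (0.685) and the heat shock list (0.688) had 1 sample high, and SELENOI (0.756) and the immediate early list (0.743) 1 sample low. No explanation was tested for these.

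Probe sets with no gene name were not used in the comparisons. With the batch as a block 13 of 11721 differed between active disease and CRM, against 0 without it.

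Patients differed from controls in 1138 genes in active disease, and 1 of 100 splits, the real one, gave as many (highest other 805). For CRM 3 of 100 splits gave at least 187 genes (highest other 624), for CR 1 of 100 gave 65 (highest other 2), and over 4 groups 1 of 100 gave 561 (highest other 3). These shares lay below the bound set for chance splits. For CRM a random split gave 624 genes, more than the real 187, so chance is not excluded for that count. A technical difference is not excluded for any of them. Controls 1 to 7 and controls 8 to 13, all controls, differed in 5557 genes, which is consistent with array batch as a source of the calls. With the ACTB ratio as a covariate, without the failed array, 0% of the 2454 active calls stayed. Their median difference went from 0.298 (median SE 0.0811) to 0.156 (0.097), and 99.3% kept direction, so the calls ended through a smaller difference and a wider spread. With the failed array in, whose ratio was 4.6, the same covariate gave 4132 calls, and the mean of the ACTB and GAPDH ratios 3536. The ratio was also higher in controls 1 to 7, so it is confounded with their batch, and a difference in RNA integrity or labelling length is open too. Within batches the median difference was 0.399 of that of the calls, between the bounds set for disease and against it, so disease cannot be told apart from batch for these genes. Selecting the genes in the fit of all arrays can by itself lower that ratio.

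Active disease and CRM differed in 0 genes without a block, as did active and CR and CRM and CR, so 100 of 100 splits gave as many in each case (highest other 4, 1977 and 1). With 5 batches as a block 109 genes differed, and 2 of 100 reassignments within batches gave as many (highest other 110). That share was below the bound set for chance, but a random reassignment gave more genes than the real labels. Chance is therefore not excluded for that count. The batches themselves were chosen after the data had been seen, and the count was 5 with 3 batches, 13 with active and CRM arrays only, 28 with array weights and 0 without a block or without active replicate 1 or CRM replicate 9.

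Platelet genes were higher in active disease than in CRM within batches, and the permutation p of 0.00015 argues against array batch as the whole source. The difference was present in 4 of 4 batches that held both groups, of which 2 had a single array in one group, and this count does not separate disease from the preparation of the blood. Blood preparations that carried over more platelets and red cells alike may also give it. With the red cell precursor mean as a covariate the platelet difference was 0.494 of its size, 0.49 (SE 0.254) against 0.991 (SE 0.241) in a fit of all 41 arrays, within 1 SE of the bound, so this cannot be told apart from disease. The prediction written for such preparations was met in both parts, a ratio below 0.5 and a rank correlation of both list means above 0.5 (0.537 within groups and batches). Only the rule that a value within 1 SE of the bound leaves it open, set after the value was seen, keeps it from counting as a fit. Within batches camera did not call the platelet list between active disease and CR (median 0.16, adjusted p = 0.229). In CRM the list lay below controls there (median -0.28, camera adjusted p = 4.75e-06, and 0.781 with an estimated correlation). In the fit of all arrays its median in CRM was 0.23 above controls. In the middle batch CRM replicates 7 and 8 (list means 8.267 and 8.706) lay above controls 8 and 9 (8.007 and 8.224). In the high mixed batch CRM replicate 9 (7.89) lay below controls 10 to 13 (8.375 to 9.006). Low values in CRM thus rest directly on CRM replicate 9 alone. Whether they add to the difference between active disease and CRM is open.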

How the results depend on the processing

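The alternatives without the failed array, with spike-in batches and without controls 1 to 7 were chosen after the data had been seen. Over the named genes, alternatives fixed beforehand gave 1661 results on the same side of the threshold, 118 stronger, 155 weaker and 1 of opposite sign; the added ones gave 449, 34, 153 and 16. The named genes counted here are the 163 printed results, a narrowing made after the wider set of 445 had been computed. Over the wider set 216 of 8031 signs changed, 142 of them within a single spike-in cluster and 74 in other settings. The cause was not tested for any count below, except where fewer genes or samples explain it.

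Main counts were 1138 genes for active disease against controls, 187 for CRM, 65 for CR, 0 between patient groups and 561 over 4 groups. A second quantile normalization gave 37 for CR and 1 for active against CR. Genes above the median level gave 235 for CR, and the mean of a gene's probe sets gave 13. Testing every probe set gave 3712, 1241, 313 and 2266 over 4 groups. Fits of only the 2 groups compared gave 477, 324 and 0. A trended, robust variance gave 90 for CRM and 19 for CR. Array weights gave 1088 for CRM, 1058 for CR, 4 for active against CR, 344 for CRM against CR and 2100 over 4 groups. A fold of at least 1.5 left 181, 17 and 34. Cell marker means as covariates gave 469, 739 and 2. The 3' to 5' ratio as a covariate gave 3536, 1842, 1101, 1 for active against CR and 2877 over 4 groups. The first residual component gave 5048, 1113, 1289, 1400 for active against CRM, 1911 for active against CR and 5321 over 4 groups. That component comes from the residuals of the same fit, so it leaves the group differences unchanged and only lowers their spread. Its counts are therefore no check on the calls. The failed array stayed in that fit. Without it and without the covariate, active against CRM gave 0 and active against CR 1. Results not listed stayed within 1.5 times their main count.

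The ACTB difference alone as a covariate, chosen after seeing the data, gave 4132 active calls with all arrays and 0 without the failed one. Without the failed array the counts were 2454, 976, 1196, 1 for active against CR and 2111 over 4 groups. With 5 spike-in batches as a block limma called 0, 0 and 0 against controls (1254, 498 and 1439 at an unadjusted p under 0.05), 109 for active against CRM and 3 over 4 groups. With 3 batches it called 757, 0, 0, 5 for active against CRM and 30 over 4 groups. Without controls 1 to 7 and the failed array it called 9, 6, 0 and 0 over 4 groups. Within the low cluster 1 gene differed between active and CRM. Within the middle cluster 0 differed from controls in any patient group. Within the high mixed cluster the counts were 1 for active, 3 for CRM and 0 for CR against controls, 3 for active against CRM and 1 for CRM against CR.

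The 109 calls between active disease and CRM became 5 with 3 clusters, 0 with no block, 28 with array weights, 13 with active and CRM arrays only, and 0 with the erythroid or the platelet mean as a covariate. Leaving out 1 array gave 0 (without active replicate 1 or CRM replicate 9) to 200 (without active replicate 8). Shared calls went from 130 to 42.5 with the controls split and 697 without the failed array for active and CRM. They went from 43 to 129.5 and 698 for active and CR, and from 13 to 25 and 334 for CRM and CR.

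Leaving out each array gave 703 (without control replicate 3) to 2454 (without active replicate 14) for active disease, 8 (without CRM replicate 3) to 378 (without CRM replicate 9) for CRM, and 0 (without CR replicate 1) to 349 (without control replicate 10) for CR. It gave 140 (without control replicate 5) to 2111 over 4 groups, 0 for active against CRM throughout, 0 to 2 for active against CR and 0 to 1 for CRM against CR.

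The groups share replicate numbers, and a replicate block gave 2933, 1936, 3893, 1 for active against CRM, 2135 for active against CR, 968 for CRM against CR and 5083 over 4 groups. Nothing in the labels pairs the samples. Active and CRM replicates 1 to 6 lie in the 2 low batches and controls 1 to 7 in their own. A replicate block thus sets arrays of different batches against each other. Active replicate 14, the failed array, is the only array of its number, so that block also takes it out of the comparisons. Of 49 pairs with the same number, 16 had a correlation over 0.1, the median was 0.0204, and 4 of 41 arrays were closest to their own number.

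Signs changed as follows. DMTN between active and CRM was -0.0597 with cell marker covariates. With 5 batches as a block the active differences were 0.0334 for KLF9, -0.0495 for LY6E and 0.00776 for MS4A7. Those in CRM were -0.10 for UBXN11, 0.21 for DDIT4, -0.0232 for LY6E, -0.10 for ITGAM and 0.00894 for UQCRB, and KLF9 was 0.0406 in CR. Without controls 1 to 7, active gave -0.0331 for BLK, 0.0386 for KLF9, -0.0744 for LY6E and 0.16 for MS4A7. CRM gave -0.11 for BLK and -0.0968 for LY6E, and CR gave 0.0790 for KLF9. Changes were sought only for lists called in the fit of all arrays or named in any case. Among genes above the median level, TNF and NF-kB in active disease was -0.0394 and granule in CRM 0.0426. Without the failed array, oxidative phosphorylation between active and CR was 0.0283, monocyte in active disease 0.14 and type I interferon between active and CRM 0.0955. With 5 batches the active median of glucocorticoid response was 0.14, and TNF and NF-kB went from 0.0237 to 0.22, where camera's direction changed but not the median's sign. The active medians of B cell and type I interferon were -0.00859 and -0.0507. Those in CRM were -0.00327 for monocyte, 0.13 for TNF and NF-kB, -0.0718 for B cell, 0.19 for immediate early and 0.00783 for oxidative phosphorylation. Those in CR were -0.16 for B cell, 0.0920 for cell cycle and -0.0783 for JAK, STAT and IL-6. Between active and CRM monocyte was 0.0412. Between active and CR heat shock was 0.0726, immediate early 0.0294, JAK, STAT and IL-6 0.0842, oxidative phosphorylation 0.0134, ribosomal 0.0246 and T cell 0.20. Between CRM and CR JAK, STAT and IL-6 was 0.0754 and TGF beta 0.00146. Lists outside this selection whose median changed sign and which camera called with 5 batches were immediate early in active disease (-0.17 to 0.32), and in CRM platelet (0.23 to -0.28) and cell cycle (-0.0597 to 0.23). Others were hypoxia between active and CRM (-0.0275 to 0.0667) and heat shock between CRM and CR (-0.0293 to 0.14). Granule between active and CR went from 0.13 to -0.10 while camera's direction stayed the same. Camera called 84 of 168 list tests, 75 without the failed array, 74 within batches and 0 with an estimated correlation, with or without the batches, so the list calls within batches named here were all lost there. Fry called no list in the fit of all arrays (lowest adjusted p = 0.32). Within batches it called only the platelet and red cell precursor lists between active disease and CRM (adjusted p = 0.0196 for both).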

Other observations

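The difference between controls 1 to 7 and the other controls, which lay in the middle and high mixed batches, was seen before it was counted. Controls 1 to 7 and controls 8 to 13 differed in 5557 genes, 2641 higher and 2916 lower in controls 1 to 7. Among the largest differences, NR4A2 was higher in controls 1 to 7 by 2.44 log2 units, RGS1 by 2.03, CD69 by 1.57 and TNFAIP3 by 1.36. TMEM176B was at -2.52, TGFB1 at -1.86 and CD79A at -1.85. Of 24 B cell genes 17 were lower. Of 25 glucocorticoid response genes 11 were higher, and of 28 immediate early genes 8 were higher and 4 lower (camera adjusted p = 0.000284 and 0.128). Of 46 oxidative phosphorylation genes 20 were higher and 5 lower (adjusted p = 0.00974). Lower genes were 14 of 29 JAK, STAT and IL-6, 10 of 21 mature neutrophil, 9 of 27 T cell and 8 of 17 MHC class I genes (adjusted p = 0.00037, 0.00037, 0.000284 and 0.000843). No values with an estimated correlation, at which every list call between the groups was lost, are given for these control lists. Of the 1138 genes called in active disease, 528 also differed between the control batches.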
